A study of Pseudomonas aeruginosa with 6 samples.

How the data were processed

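The series holds 6 RNA-seq libraries of Pseudomonas aeruginosa F9676, 3 mock and 3 treated with 0.04% acetic acid for 4 h. Per the labels' protocols, RNA was depleted of ribosomal RNA with probes, and second-strand cDNA was marked with dUTP and degraded, so the library type keeps the strand. Whether the gene counting used the strand is not given in the sources used here, so antisense and overlapping genes are uncertain. Bowtie2 2.2.3 and HTSeq 0.6.1 are named in the submitters' processing notes, with no settings.

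One deposited table covers all libraries with 5881 genes on a single reference chromosome, and groups were taken from the sample titles. Raw counts per gene were deposited by the authors, per the file headers, as whole numbers. FPKM values were also deposited by the authors, and for each library, count divided by FPKM and gene length is 1 constant. The deposited signal columns are counts that the authors divided by 1 size factor per library. The authors' deposited log2 fold changes, p-values and adjusted p-values come from a test that is not given in the sources used here, and 40 genes have none. Gene lengths and 1-based coordinates are those deposited by the authors, and the name of the assembly is not given in the sources used here. A symbol was present for 1808 genes, and 361 more took the symbol of the P. aeruginosa Swiss-Prot entry quoted in the deposited description. RefSeq names of a P. aeruginosa reference served only to turn locus tags in those entries into symbols.

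The main comparison used the deposited counts in edgeR 4.0.16 (R 4.3.3): filterByExpr with its defaults, TMM factors, robust dispersion and glmQLFit, glmQLFTest for acetic acid against mock, two-sided, and Benjamini-Hochberg adjustment over the 5673 genes kept, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM use the TMM factors, and their errors are SD over 3 libraries. The numbers 1 to 3 are shared by both groups but nothing says that they mark a shared culture, so the design has no block. Totals were 2773914 to 3041109 gene counts per library, and 0 pairs of libraries were identical.

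Before the data were examined, 23 gene lists of 499 symbols were fixed, and 437 genes matched while 84 symbols did not. An RNA helicase that shares the symbol of the rhamnolipid gene rhlB was left out of the exoproduct list. The list of envelope stress holds bfiR, which encodes a biofilm regulator. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists. Named genes follow a rule fixed beforehand. Among called genes with no overlap between groups, a mean of at least 10 CPM in the higher group and a symbol in the table, the 6 largest rises and the 6 largest falls were taken. In each list the member with the smallest p was added, 2 where the list passed camera, and 3 for acetate. Other members are named to complete a count and were chosen after their values were seen.

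Background was the median count per kilobase of the 5% of genes, 500 bp or longer, that were weakest in the other 5 libraries. On data simulated for acetic acid against mock with 5673 genes, of which 200 were changed, the test recovered 32% of 2-fold and 66% of 4-fold changes, 5.8% of its calls were false, and 0 genes were called when no gene was changed. A shifted list was recovered with a camera p of 2.34e-32 and 0 of 30 unchanged lists were called. Genes were simulated independently of each other and these lists were random, so this result cannot speak for lists whose genes move together. Simulated rises and falls were equal in number, and the simulated libraries did not differ in background. The share of false calls therefore need not hold for the real libraries, which differ in background. An even background of 60 counts per kilobase added to 1 library was recovered as 59.6.

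Alternatives fixed beforehand were RLE and upper-quartile factors, library sizes alone, DESeq2 1.42.0, no filter, a mean count of at least 50, the replicate number as a block, each library left out, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and no rRNA or tRNA genes. Those added after seeing the data subtracted the background once or 1.5 times, subtracted it and left out acetic acid library 2, left out acetic acid libraries 2 and 3, used the log2 background as a covariate, or left out ssrA, rnpB and ffs too. Without acetic acid libraries 2 and 3 the treated group holds 1 library. GC content was not checked, since no genome sequence was used here. Figures were drawn with matplotlib 3.10.9.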

Results

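Transcript levels were measured by RNA sequencing in Pseudomonas aeruginosa F9676, a wild-type strain of this Gram-negative bacterium, in shaken LB cultures at 28 °C. Cultures set to an OD of 0.01 received acetic acid to 0.04% or served as the mock group at 0.00%, and cells were collected 4 h later. There were 3 libraries per group, and the question set by the series was how acetic acid changes gene expression in this organism. Whether the 3 libraries of a group came from separate cultures is not stated, so the p-values measure only the spread between these samples, which may be technical. Total gene counts were 2828717, 2817119 and 2773914 in mock libraries 1, 2 and 3, and 2848405, 2896404 and 3041109 in acetic acid libraries 1, 2 and 3. The level of the weakest genes differed far more than depth did. It was 17, 12.4 and 5.6 counts per kilobase in the mock libraries and 8.5, 67.9 and 22.2 in the acetic acid libraries, and spread over all genes it would take 13.5% of the counts of acetic acid library 2 against 1.2% to 4.2% elsewhere. Principal component 1 of log2 CPM, with 63.9% of the variance, ordered the libraries as this background did and did not part the groups. It stood at -2.5, -15.5 and -58.1 in mock libraries 1, 2 and 3, and at -19.9, 71.2 and 24.9 in the acetic acid libraries. Component 2, with 27.6%, parted the groups, at 11.5 to 25.5 in mock and -49.9 to 7.6 with acetic acid.

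**Figure D1:**
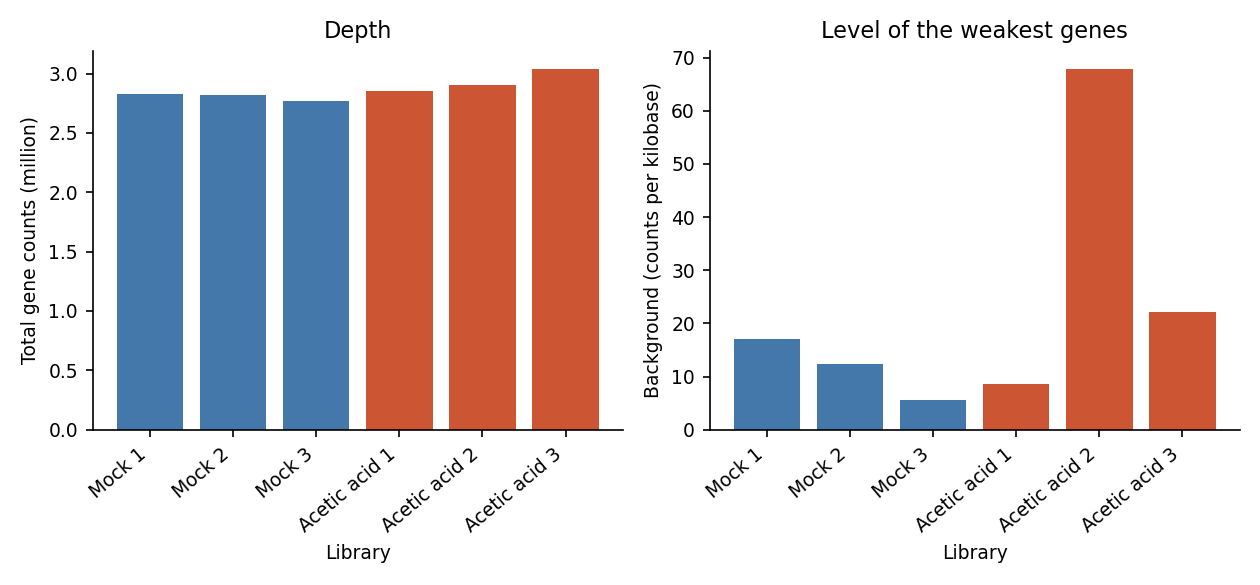
Left, total gene counts of each library, and right, background in counts per kilobase, the median over the weakest genes of 500 bp or more. Bars are single libraries, blue for mock and red for acetic acid; totals lie between 2773914 and 3041109, while the background of acetic acid library 2 stands at 67.9.

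After acetic acid, most tested genes for branched-chain and aromatic amino acid breakdown and for quorum-regulated exoproducts were lower. Among genes with a symbol, the largest changes included a pilin gene among the falls. Among the rises were genes annotated for polyamine synthesis, lactate use and a biofilm two-component system, which were not tested as groups. Among called genes with a symbol, no overlap between the groups and a mean of at least 10 CPM in the higher group, the largest fall was that of flp (ADJ52_RS04710, 1034707 to 1034925), the major pilin of the Flp pilus. Its normalised count, scaled to CPM with TMM factors, was 1689 ± 286 in mock and 24.9 ± 7.84 with acetic acid (SD, n = 3), a log2 fold change of -6.08 ± 0.35 (SE, adjusted p = 5.03e-05). Next came 3 adjacent genes of homogentisate breakdown, maiA (ADJ52_RS11630) at -4.69 ± 0.40, hmgA (ADJ52_RS11640) at -4.35 ± 0.38 and fahA (ADJ52_RS11635) at -4.17 ± 0.48, which lie between 2529469 and 2532705. The galactose-binding lectin gene lecA (ADJ52_RS14640, 3282859 to 3283227) fell from 512.5 ± 33.2 to 29.5 ± 9.4 CPM (SD, n = 3, log2 fold change -4.12 ± 0.29, SE). The 3-hydroxybutyrate dehydrogenase gene bdhA (ADJ52_RS11610, 2524058 to 2524828) fell by 4.00 ± 0.28 on the log2 scale.

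The largest rise by the same rule was that of speB (ADJ52_RS08225, 1799905 to 1800864), annotated as agmatinase, an enzyme of the route from agmatine to putrescine. It went from 5.83 ± 3.02 to 65.3 ± 6.87 CPM (SD, n = 3), a log2 fold change of 3.45 ± 0.39 (SE, adjusted p = 0.001). Its mock level was low, and the log2 fold change ran from 3.12 to 6.88 over the 22 alternatives, so its size depends on the processing. The repressor gene qapR (ADJ52_RS27465, 6004772 to 6005629) rose by 2.32 ± 0.32, and speD (ADJ52_RS02165, 485267 to 485749), an adenosylmethionine decarboxylase gene of spermidine synthesis, by 2.31 ± 0.46, or by 2.23 and 2.28 without mock library 2 or acetic acid library 3, where it did not pass. The L-lactate dehydrogenase gene lldD (ADJ52_RS02175, 489163 to 490308) rose by 2.28 ± 0.20. The adjacent genes bfiS (ADJ52_RS23360) and bfiR (ADJ52_RS23355), which encode the sensor and the response regulator of a biofilm two-component system at 5130954 to 5133877, each rose by 2.18, with standard errors of 0.22 and 0.24.

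**Figure D2:**
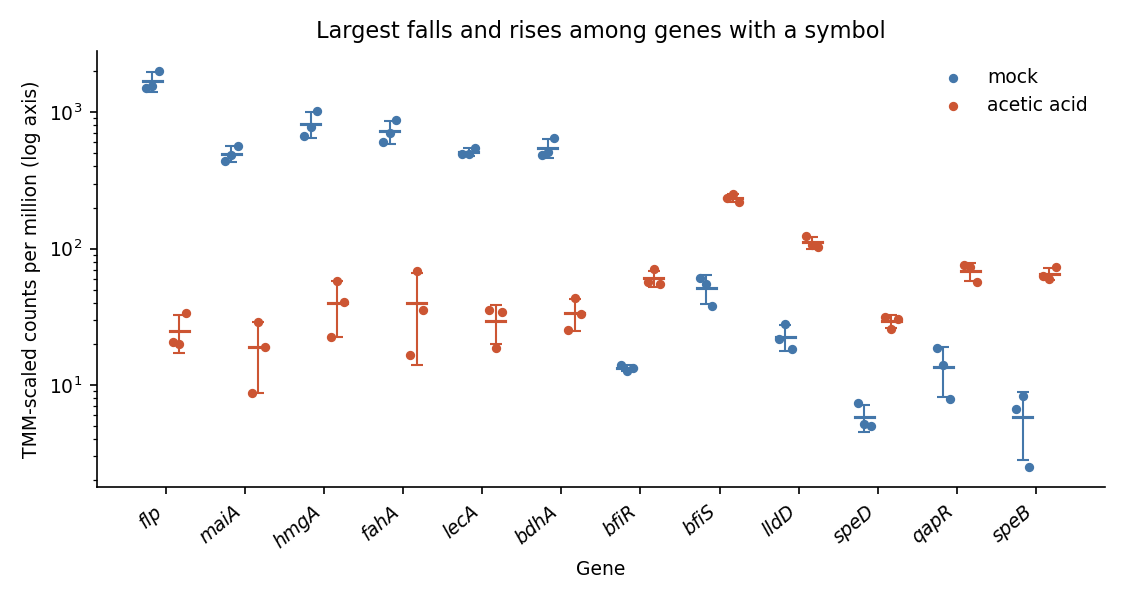
Normalised CPM (log axis) of the 6 largest falls and the 6 largest rises among called genes with a symbol, no overlap between the groups and a mean of at least 10 CPM in the higher group. Points are single libraries, horizontal lines are group means and bars are SD (n = 3), blue for mock and red for acetic acid; of the 12, flp shows the widest gap at a log2 fold change of -6.08.

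Of 5673 genes tested with edgeR's quasi-likelihood test, 240 were higher and 582 lower with acetic acid at a Benjamini-Hochberg adjusted p under 0.05. Changes of 1 log2 unit or more were seen in 112 of the higher and 461 of the lower genes. Of such changes, 66 were rises without mock library 2 and 200 without acetic acid library 1. The groups did not overlap in 1939 genes, where chance alone would give 10% of the genes tested on average over all splits. Genes that move together can give far more or fewer in a single split, and the other splits were not counted for this. The biological coefficient of variation was 36.8%. Decreases made up 70.8% of the calls with TMM scaling, 79% with RLE factors, 45.2% with upper-quartile factors and 24.4% with library sizes alone. These scalings placed the median log2 change of all tested genes at 0.24, 0.17, 0.45 and 0.72, so directions below are relative to TMM, and no called gene changed sign under any of them. Without acetic acid library 2, 600 genes were higher and 796 lower, a share of decreases of 57%. Higher calls numbered 96, 72 and 116 without mock library 1, 2 or 3 and 96 without acetic acid library 3, and lower calls numbered 374, 362 and 358 without mock library 2, mock library 3 or acetic acid library 3. The authors' deposited table lists 219 genes higher and 711 lower at an adjusted p under 0.05, and 759 of the genes called here were called in that deposited table in the same direction. Another 63 were called only here and 171 only there. Both sets of calls rest on the same libraries, so their overlap is no independent check.

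**Figure D3:**
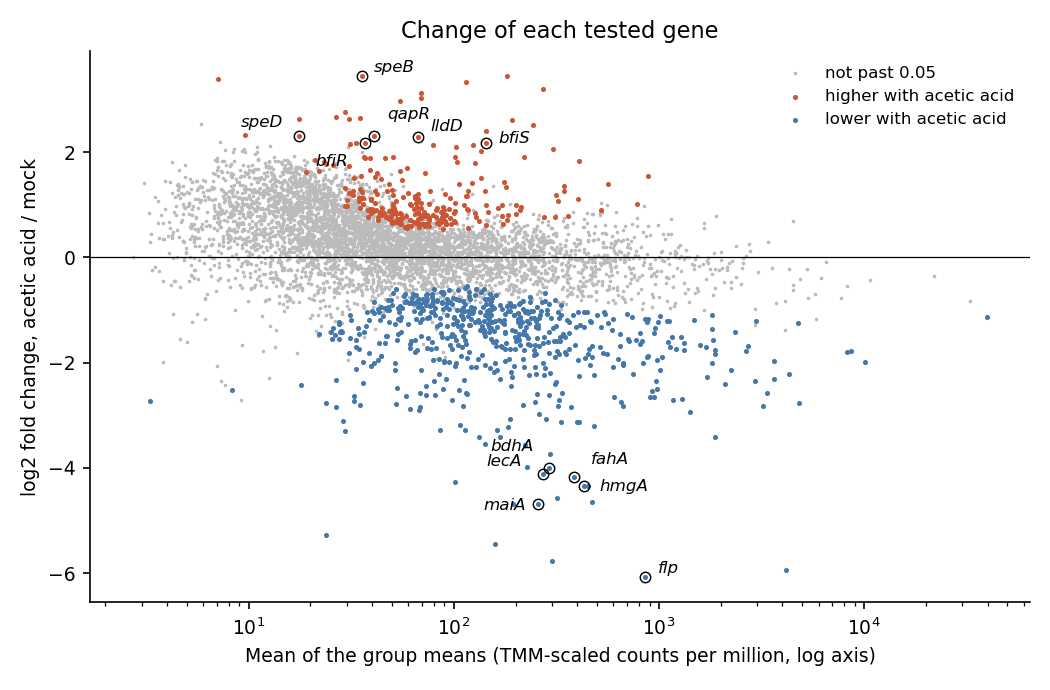
Fitted log2 fold change of each of the 5673 tested genes against its mean normalised CPM (log axis). Red points are the 240 genes higher and blue points the 582 genes lower with acetic acid at an adjusted p under 0.05, grey points did not pass, and circles mark the 6 largest falls and 6 largest rises among called genes with a symbol and no overlap between the groups; grey points at the weak end sit mostly above 0, where the background of acetic acid library 2 weighs most.

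Catabolism of branched-chain and aromatic amino acids had the smallest camera p at the preset correlation among the 23 gene lists that had been fixed beforehand. Of 26 genes tested, 17 fell and none rose, or 20 fell when adjusted over the list alone, with a median log2 fold change of -1.67 (camera adjusted p = 3.27e-19, or 0.637 with an estimated correlation). Besides maiA, hmgA and fahA, the decreases included liuA (ADJ52_RS11670), the isovaleryl-CoA dehydrogenase of leucine breakdown, at -2.74 ± 0.32, mmsA (ADJ52_RS19875) of valine breakdown at -3.41 ± 0.40, and hppD (ADJ52_RS05800), which forms homogentisate from the tyrosine keto acid, at -2.65 ± 0.32. Histidine genes of the same list did not pass over all genes.

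Genes for quorum-regulated exoproducts were lower as well. Of 12 tested, 8 fell and none rose, or 9 fell when adjusted over the list alone, with a median of -1.87 (camera adjusted p = 3.38e-11, or 0.637 with an estimated correlation). In several alternatives some members passed as higher. There were 3 with upper-quartile factors, library sizes alone, 1.5 times the background subtracted, subtraction without acetic acid library 2, or the covariate. Without acetic acid library 2 there were 2, and with the background subtracted 1. Between 6 and 9 fell in each of the 22. Besides lecA the decreases included 3 protease genes. Protease IV (piv, ADJ52_RS23250) fell by 3.41 ± 0.30 from 3412 ± 767 to 322 ± 54.8 CPM (SD, n = 3), lasA (ADJ52_RS10955) had a log2 fold change of -2.70 ± 0.30, and the elastase gene lasB (ADJ52_RS20875) one of -2.34 ± 0.30. The rhamnolipid gene rhlA (ADJ52_RS19510, -0.75 ± 0.30) and the cyanide gene hcnA (ADJ52_RS12595, 0.59 ± 0.25) did not pass, with adjusted p-values of 0.153 and 0.175. Both passed in some alternatives, rhlA without acetic acid library 1 (-1.11) and hcnA without acetic acid library 2 (0.83) among them. Of the 17 tested genes for the las, rhl and pqs signals and receptors, 2 rose and 1 fell, or 5 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.772, upward, against a median of -0.02). The decrease was that of rsaL (ADJ52_RS30620), the repressor next to lasI, at -1.20 ± 0.30. The rises were those of phnA (ADJ52_RS06460) at 1.02 ± 0.27 and pqsE (ADJ52_RS06455) at 0.91 ± 0.24 in the quinolone signal locus. The regulator gene lasR (ADJ52_RS08270) stood at -0.99 ± 0.30 with an adjusted p of 0.0605. It passed as lower in 13 of the 22 alternatives, DESeq2 (-1.04), both limma fits (-1.13) and the fits without acetic acid library 1 (-1.42) or 2 (-0.73) among them. The signal synthase gene lasI (ADJ52_RS08280) stood at -0.02 ± 0.27. The fall of rsaL did not pass without mock library 2 (-1.26), mock library 3 (-0.99) or acetic acid library 3 (-1.29). Neither rise passed with RLE factors or when any library except acetic acid library 2 was left out, and without that library 7 rose and 4 fell, while with library sizes alone 8 rose.

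Secretion systems did not move as one. Of 18 type III secretion genes, 7 fell and none rose, or 9 fell when adjusted over the list alone, with a median of -0.67 (camera adjusted p = 0.000564, or 0.637 with an estimated correlation). The translocon genes popB (ADJ52_RS10080) and popD (ADJ52_RS10085), at 2190697 to 2192768, stood at -2.14 ± 0.18 and -2.09 ± 0.18, and the effector genes exoS (ADJ52_RS21570) and exoT (ADJ52_RS26875) stood at -1.92 ± 0.24 and -0.62 ± 0.17. The call of exoT was lost in 7 alternatives, with upper-quartile factors (-0.40), library sizes alone (-0.13) or the replicate block (-0.63), and without mock library 1 (-0.66), 2 (-0.67) or 3 (-0.54) or acetic acid library 3 (-0.63). The master regulator gene exsA (ADJ52_RS10105) had a value of 0.39 ± 0.30 and did not pass, but did at 0.68 without acetic acid library 2. With library sizes alone 2 genes of this list rose and 4 fell, and 3 or 4 fell when mock library 1, 2 or 3 or acetic acid library 3 was left out. Among 24 type VI secretion genes, 8 rose and 4 fell, or 10 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.353). For changes in either direction, fry gave this list an adjusted p of 6.6e-05. All 4 decreases lay at 2975780 to 2987980, led by the sheath genes tssB (ADJ52_RS13570, -2.21 ± 0.26) and tssC (ADJ52_RS13575, -2.20 ± 0.28). Most rises lay at 5819405 to 5842224, among them tssF (ADJ52_RS26660, 1.00 ± 0.16), tssM (ADJ52_RS26715, 0.78 ± 0.18) and the spike gene vgrG1a (ADJ52_RS26645, 0.76 ± 0.18), and the last 2 lost significance in 6 and 9 alternatives. The list held 2 rises without mock library 1, mock library 3 or acetic acid library 1, 1 without mock library 2 or acetic acid library 3, and 13 without acetic acid library 2, with 4 decreases each time.

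**Figure D4:**
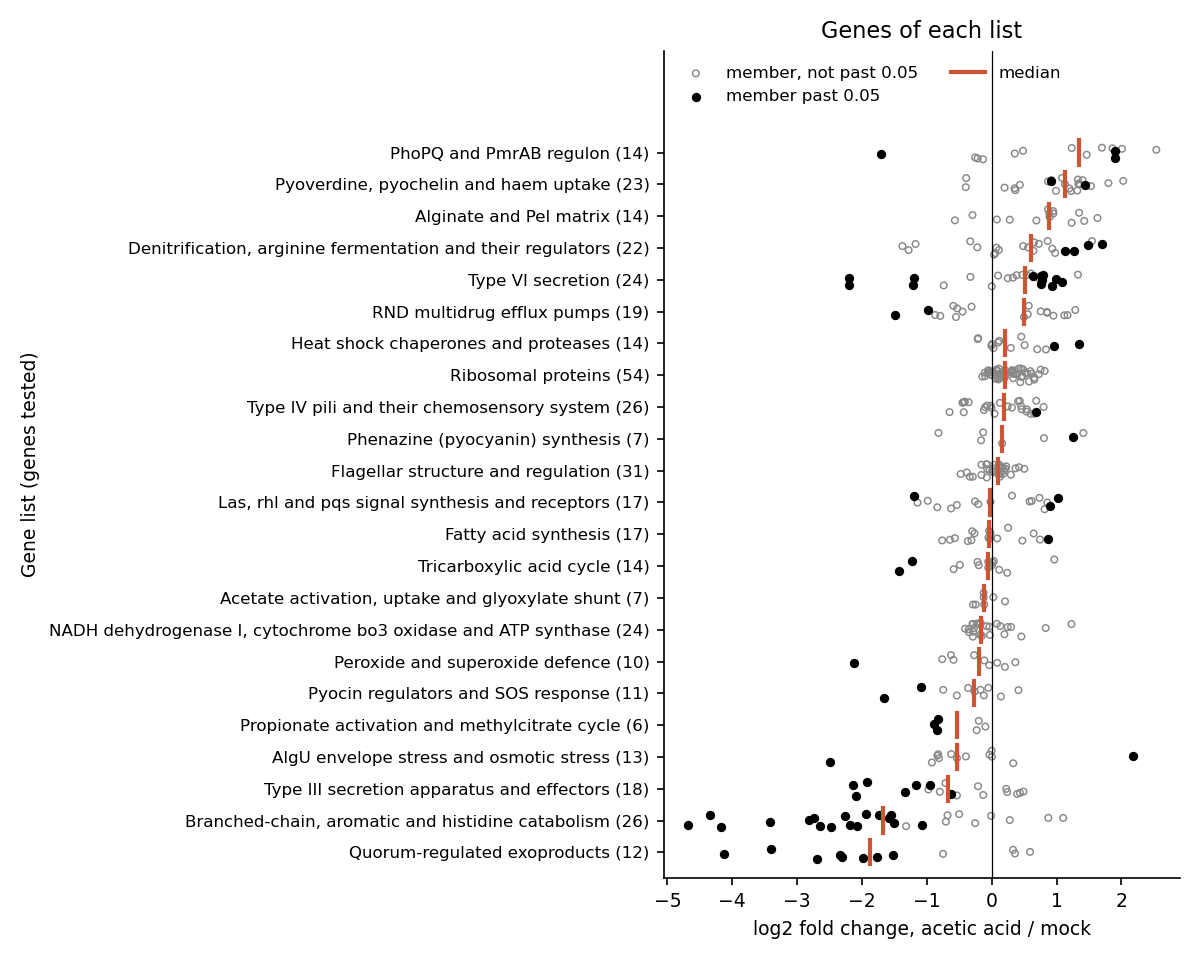
Log2 fold change of each member of the 23 gene lists, with the number of genes tested in brackets. Filled points passed an adjusted p of 0.05 over all genes, open points did not, and the red bar is the list median; the medians of quorum-regulated exoproducts (-1.87) and of branched-chain and aromatic catabolism (-1.67) lie farthest from 0.

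No listed gene of acetate activation or of the glyoxylate shunt passed in edgeR. Of 7 tested, 0 were called over all genes or over the list alone, 0 had an unadjusted p under 0.05, and 0 were called by DESeq2 or limma. Acetyl-CoA synthetase (acs, ADJ52_RS02375) had 88.8 ± 11 CPM in mock and 74.7 ± 12 with acetic acid (SD, n = 3), a log2 fold change of -0.25 ± 0.18. The isocitrate lyase gene aceA (ADJ52_RS14980) stood at -0.29 ± 0.26 and the isocitrate dehydrogenase kinase gene aceK (ADJ52_RS09115) at -0.12 ± 0.15. The list median was -0.12 (camera adjusted p = 0.772), 0.09 with upper-quartile factors and 0.33 with library sizes alone, where 2 of the 7 rose. Acs passed as lower with 1.5 times the background subtracted (-0.55) and with subtraction and without acetic acid library 2 (-0.46). The acetate kinase gene ackA (ADJ52_RS05650) passed as higher with library sizes alone (0.66) and with the background as a covariate (0.57). It stood at 0.63 without acetic acid libraries 2 and 3, which leaves 1 acetic acid library. The symbol actP was not matched, and the genes described as cation acetate symporters, ADJ52_RS18240 (-0.33 ± 0.21) and ADJ52_RS12770 (0.07 ± 0.55), did not pass. In the neighbouring propionate list, 3 of 6 genes fell, over all genes and adjusted over the list alone: prpD (ADJ52_RS05445, -0.89 ± 0.20), prpC (ADJ52_RS05460, -0.84 ± 0.22) and prpB (ADJ52_RS05465, -0.85 ± 0.24) of the methylcitrate cycle (camera adjusted p = 0.118). None of the 3 passed with library sizes alone or without mock library 2, mock library 3 or acetic acid library 3, although all stayed below 0, and prpC also missed without mock library 1 (-0.94) and prpB with upper-quartile factors (-0.61). In that order prpD stood at -0.39, -0.94, -0.76 and -0.89, prpC at -0.36, -0.86, -0.70 and -0.98, and prpB at -0.35, -0.82, -0.68 and -1.02. Of 14 tricarboxylic acid cycle genes, 2 fell on both counts, the fumarase gene fumC1 (ADJ52_RS05740, -1.23 ± 0.25) and the aconitase gene acnA (ADJ52_RS09335, -1.43 ± 0.32), with a camera adjusted p of 0.353. Neither passed without mock library 2, mock library 3 or acetic acid library 3.

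Denitrification and fermentation genes held 4 rises and no decrease among 22 tested, or 6 rises and 3 decreases when adjusted over the list alone (camera adjusted p = 0.15). They were the nitrous oxide reduction genes nosR (ADJ52_RS19060, 1.71 ± 0.26), nosD (ADJ52_RS19070, 1.48 ± 0.27) and nosZ (ADJ52_RS19065, 1.27 ± 0.31), and ADJ52_RS24460 (1.13 ± 0.32), described as a VWA domain protein. The last 2 did not pass without mock library 1, 2 or 3 or acetic acid library 3, and ADJ52_RS24460 lost its call in 10 of the 22 alternatives in all, RLE (1.04) and upper-quartile factors (1.34) included. In this list 9 rose without acetic acid library 2. It does not hold the 6 genes of periplasmic nitrate reductase with napA at 1610211 to 1614794, which were lower (median -1.56). In the PhoPQ and PmrAB list, 2 of 14 rose and 1 fell, or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.17). The spermidine synthase gene speE2 (ADJ52_RS02160) beside speD rose by 1.91 ± 0.36, and arnA (ADJ52_RS19780), which modifies lipid A with aminoarabinose, by 1.90 ± 0.38. The lipid A deacylase gene pagL (ADJ52_RS02860) fell by 1.71 ± 0.29 from 2610 to 797 CPM. The rise of speE2 did not pass without acetic acid library 3 (1.85). Siderophore and haem genes held 2 rises among 23, the pyochelin receptor gene fptA (ADJ52_RS23480, 0.91 ± 0.19) and the pyochelin synthesis gene pchF (ADJ52_RS23500, 1.43 ± 0.39), of which 1 passed when adjusted over the list alone (camera adjusted p = 0.118). Neither passed without mock library 1, mock library 2 or acetic acid library 3, pchF lost its call in 6 alternatives, without mock library 3 among them, and 8 genes of this list rose without acetic acid library 1. The medians of the PhoPQ and PmrAB, siderophore, and alginate and Pel lists were 1.35, 1.13 and 0.89, and 0.60, 0.49 and -0.15 without acetic acid library 2, whose background was the highest.

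No stress list passed camera at the preset correlation, while fry for changes in either direction passed the envelope (adjusted p = 0.00421), oxidative (0.00482) and pyocin and SOS (0.0225) lists. Heat shock genes held 2 rises among 14 on both counts, htpG (ADJ52_RS09510), a chaperone gene that went from 192.8 ± 19.8 to 492.1 ± 119 CPM (SD, n = 3, log2 fold change 1.35 ± 0.24, SE), and the protease gene hslV (ADJ52_RS00730, 0.96 ± 0.20), with a camera adjusted p of 0.145. Neither passed without mock library 2, hslV did not without mock library 1 or acetic acid library 3, and 6 rose without acetic acid library 2. With library sizes alone 11 rose. Over the 22 alternatives camera passed the heat shock list in 7 (adjusted p from 0.000251 to 0.611), the envelope list in 2 (0.0194 to 0.861), the pyocin and SOS list in 1 (0.0462 to 0.837) and the oxidative list in 0 (0.16 to 0.409). Of 10 oxidative stress genes, 1 fell on both counts, the catalase gene katE (ADJ52_RS12355, -2.13 ± 0.41, camera adjusted p = 0.286). It did not pass without mock library 3 (-2.08) or with library sizes alone (-1.58), and its value ran from -5.5 to -1.58 over the 22 alternatives. The envelope and osmotic stress list had 1 rise, that of bfiR, and 1 decrease, the osmotically regulated gene osmE (ADJ52_RS01635, -2.50 ± 0.27), or 1 and 5 when adjusted over the list alone (camera adjusted p = 0.118), and 5 and 3 genes of it fell without acetic acid library 1 or 2. Of 11 pyocin and SOS genes 2 fell on both counts, the pyocin genes pys2 at 4367086 (ADJ52_RS30515, -1.67 ± 0.26) and at 1580639 (ADJ52_RS30440, -1.09 ± 0.26), the latter described in the table as a hypothetical protein, with a camera adjusted p of 0.145. That gene did not pass without mock library 2, mock library 3 or acetic acid library 3, and 5 fell without acetic acid library 1.

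Of 19 efflux genes, 2 fell on both counts, mexG (ADJ52_RS23400, -1.49 ± 0.29) and the repressor gene mexR (ADJ52_RS24970, -0.99 ± 0.26), and the list's median of 0.50 and mean of 0.11 were opposite in sign to its downward camera test (adjusted p = 0.677). Neither passed without mock library 3 or with library sizes alone (-0.97 and -0.55), and mexR did not without mock library 1, mock library 2 or acetic acid library 3 or with upper-quartile factors (-0.79). In this list 4 fell without acetic acid library 1, and 2 rose and 5 fell without acetic acid library 2. Only 7 of 16 phenazine genes had enough counts to be tested, and the rise of phzA (ADJ52_RS11095, 1.25 ± 0.25) is uncertain. P. aeruginosa carries near-identical phenazine operons, whose shared reads may not have been counted. Of the 7, 1 rose over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.606). The rise of phzA did not pass without mock library 1, 2 or 3 or acetic acid library 3.

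Fatty acid synthesis held 1 rise among 17 on both counts, the enoyl reductase gene fabI (ADJ52_RS10615, 0.87 ± 0.21, camera adjusted p = 0.861). Type IV pili held 1 among 26, pilK (ADJ52_RS25030, 0.69 ± 0.19), which lost significance in 11 alternatives, with none when adjusted over the list alone (camera adjusted p = 0.486). The list leaves out the Flp pilus, described as a type 4b pilus, where flp stood at -6.08 and 9 genes beside it had a median of -3.29. With single libraries left out, fabI and pilK passed only without acetic acid library 2. There 4 and 12 genes of these lists rose. In edgeR, 0 of 54 ribosomal protein genes, 0 of 31 flagellar genes, 0 of 24 respiratory chain genes and 0 of 14 alginate and Pel matrix genes passed over all genes or over the list alone, with 6, 1, 0 and 0 at an unadjusted p under 0.05. DESeq2 called 1 ribosomal gene and none in the other 3 lists, and limma called none in any of the 4. The smallest p-values there belonged to rplS (ADJ52_RS20970, 0.82 ± 0.25), flgI (ADJ52_RS06895, 0.42 ± 0.18), cyoE (ADJ52_RS08870, 1.23 ± 0.65) and alg44 (ADJ52_RS19720, 1.43 ± 0.83), and the camera adjusted p-values were 0.118, 0.772, 0.697 and 0.539. Over the 22 alternatives camera passed the ribosomal list in 9 (adjusted p from 1.44e-09 to 0.788), the flagellar list in 3 (0.00314 to 0.972) and the other 2 lists in 0 (0.334 to 0.956 and 0.143 to 0.941). The respiratory chain list covered only NADH dehydrogenase I, cytochrome bo3 oxidase and ATP synthase. Outside it, 4 adjacent genes at 5057255 to 5062501 were lower (median -1.89), among them ccoN of a cbb3-type cytochrome c oxidase. That stretch was picked after its values were seen. The matrix list held 12 alginate and 2 Pel genes, since none of its 12 psl symbols was matched. A stretch of 11 genes at 2817189 to 2831185 that includes a gene described as the biofilm formation protein PslJ (ADJ52_RS12950, -1.12 ± 0.17) was lower throughout, with a median of -1.57. In the alternatives 10 or 11 of its genes were lower, 10 with library sizes alone. Without acetic acid library 2, 22 ribosomal genes and flgI (0.56) rose, and with library sizes alone 41 ribosomal and 20 flagellar genes did.

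Of the 23 lists, 3 passed with camera's preset correlation and 0 with an estimated one. Directional fry passed the same 3, with adjusted p-values of 0.0193 for catabolism, 0.025 for exoproducts and 0.0132 for type III secretion. The group results above are counts of called members, which are no test of a group, since neighbouring genes move together. Of the 7 lower type III genes, 5 lie in 1 stretch at 2189317 to 2193331. Over all 5673 genes tested, 582 were lower and 240 higher. The 3 lists that passed held larger shares of lower genes, at 17 of 26, 8 of 12 and 7 of 18. Counts such as 2 of 19 efflux or 1 of 10 oxidative stress genes lower lie near the share over all genes. The preset test also passed 4 to 18 lists in each of the 9 other ways to divide the 6 libraries into 3 and 3. Among the lists not yet given such counts, camera passed type IV pili in 5 alternatives (adjusted p from 0.000208 to 0.785), siderophores in 3 (0.000464 to 0.861), propionate in 3 (0.0215 to 0.242), denitrification in 2 (0.00254 to 0.396) and quorum signals in 1 (0.0239 to 0.972).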

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

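Among the tests here, those with the background, without acetic acid libraries 2 and 3 together, and without ssrA, rnpB and ffs were chosen after the data were seen. Leaving out acetic acid libraries 2 and 3 leaves 1 acetic acid library, so the spread in that fit comes from the mock libraries alone. It is included in totals and ranges over the 22 alternatives, and the 1 pass of the quorum signal list was its own. Over the 22 alternatives, between 446 and all 822 of the called genes were called again in the same direction, none of the 822 changed sign, and 379 genes (69 higher, 310 lower) passed in every one. Higher genes numbered 240 in the comparison as reported, 676 with upper-quartile factors, 1370 with library sizes only, 154 without ssrA, rnpB and ffs, 468 with 1.5 times the background subtracted, 681 with the background subtracted and acetic acid library 2 left out, 1001 without acetic acid libraries 2 and 3, and 1002 with the background as a covariate. Lower genes numbered 582, against 911 with 1.5 times the background subtracted, 999 with subtraction and without acetic acid library 2, and 934 with the covariate. Genes higher by 1 log2 unit or more numbered 112, against 204 with upper-quartile factors, 490 with library sizes only, 237 without acetic acid libraries 2 and 3 and 170 with the covariate. Those lower by as much numbered 461, against 253 with library sizes only. Leaving out single libraries gave 72 (without mock library 2) to 600 (without acetic acid library 2) higher genes, 358 (without acetic acid library 3) to 840 (without acetic acid library 1) lower genes, 66 (without mock library 2) to 200 (without acetic acid library 1) higher by 1 log2 unit, and 321 (without mock library 3) to 624 (without acetic acid library 1) lower by 1 log2 unit. Gene lists past the threshold numbered 3, against 5 with upper-quartile factors, 7 with library sizes only and 5 with limma on log2(FPKM + 1). They numbered 6 with 1.5 times the background subtracted, 6 with subtraction and without acetic acid library 2, and 8 with the covariate. With an estimated correlation 0 passed, with directional fry 3, and with fry for changes in either direction 13. Single libraries left out gave 3 to 6. The 3 lists that passed did so in all 22 alternatives of the fit. Why these counts moved was not tested. Whether the replicate numbers pair the samples cannot be told from the libraries. The deviations of same-numbered libraries correlated at -0.732, 0.462 and -0.058, and those of differently numbered ones at -0.754 to 0.765. Deviations from a mean of 3 libraries constrain each other, so these values cannot exclude a shared culture. With the replicate block 179 genes were higher and 580 lower, 102 and 465 of them by 1 log2 unit or more, and 3 lists passed. Over the 75 named genes, 1648 values were compared. Direction and side of the threshold held in 1412, significance was lost in 129 and gained in 67, and 40 changed sign, and 32 genes kept direction and side in every alternative. The changes of sign fell on 10 genes that were not called as reported, 7 of them for acetate use. Only glcB (0.33) and lasI (0.41), both with library sizes only, also passed after the change. With library sizes only the others were acs (ADJ52_RS02375, 0.25), aceK (0.35), aceA (0.17) and pta (0.33). With upper-quartile factors they were aceK, pta and glcB at 0.09 each and lasI at 0.18. With the covariate they were aceA (0.01), pta (0.26), glcB (0.13), lasI (0.25) and alg44 (-0.23). Without acetic acid libraries 2 and 3 they were pta (0.32), glcB (0.16), lasI (0.45) and alg44 (-0.97). With subtraction and without acetic acid library 2 they were pta (0.04) and lasI (0.12), and with 1.5 times the background lasI (0.01). The acs gene ADJ52_RS05910 changed to -0.04 with RLE factors and with DESeq2, to -0.03 with a mean count of at least 50, to -0.01 in both limma fits and to -0.09 without ssrA, rnpB and ffs. With single libraries left out, that gene ran from -0.18 (without mock library 1) to 0.34 (without mock library 3), ackA from -0.12 to 0.46, pta from -0.46 to 0.11, glcB from -0.36 to 0.06, lasI from -0.39 to 0.20 and exsA from -0.04 to 0.68, the lower value of these 5 always without acetic acid library 1. At 2773914 to 3041109 counts and 3 libraries per group, 32% of simulated 2-fold changes were recovered.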

Other observations

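Several neighbourhoods moved together, and those named were picked after their values were seen. On 1 strand, 31 stretches of at least 4 adjacent genes were called in the same direction, 8 higher and 23 lower. They held 176 genes in all, members of the gene lists among them. The calls shuffled 1000 times gave at most 3 stretches. These shuffles moved single genes and so broke up neighbours that share a transcript, so the excess is not shown to be particular to acetic acid. Beside flp, 9 genes at 1035334 to 1044503, rcpC to tadG, which build the Flp pilus, had a median log2 fold change of -3.29. Near lasA, 4 genes at 2373610 to 2386369 for an Ig-like repeat protein and a type I secretion system had the lowest median, -4.61. A polysaccharide cluster of 11 genes at 2817189 to 2831185, with the gene described as PslJ, was lower (median -1.57), as were 13 genes with several phage tail genes among them at 5250537 to 5262430 (-1.88), 8 genes of a second chemotaxis cluster with aer2 and cheB2 at 5726489 to 5735307 (-1.66), and 6 genes of periplasmic nitrate reductase with napA at 1610211 to 1614794 (-1.56).

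Sugar genes parted at 3.97 to 3.98 Mb. The porin gene oprB and 4 sugar transport genes at 3970180 to 3975914 were lower (median -2.23), while the adjacent stretch gtrS, gltR, glk and edd at 3976439 to 3981571, for glucose sensing and the Entner-Doudoroff route, was higher (median 1.73). The highest median among rising stretches, 2.64, was that of 5 genes at 6000599 to 6005629 for a permease, a glutamine synthetase family protein, hydrolases and qapR. Rising by a median of 2.28 were 5 genes at 484140 to 492145, speE2 and speD beside lldD and a lactate permease gene.

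Of the tests below, those of the origin gradient, library size, shared response, the library left out, library sizes on the 2 lists and on changes of 1 or 2 log2 units, and the number of genes called in other splits were chosen after the result was seen. Weak genes read higher in acetic acid library 2. Its total was 1.01 times the mean of the other 5 libraries, which argues against depth, and acetic acid library 1 had a background of 8.5 counts per kilobase, below mock libraries 1 and 2 at 17 and 12.4 and above mock library 3 at 5.6, which argues against a response shared by the treated samples. Genomic DNA is a candidate explanation: over 902 weak genes, the excess over the mock mean was 1.42 times as high in the 181 genes nearest dnaA, the origin side, as in the 181 farthest (95% bootstrap interval 1.25 to 1.65). The interval comes from resampling single genes, and since neighbouring genes move together it may be too narrow. All 6 libraries showed such a gradient, with ratios of 1.26 to 1.46, and weak transcription that follows gene copy number could give it too, which stays open because the table holds no counts by strand.

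Most of the larger changes were decreases, 80.5% of those of 1 log2 unit or more. Without acetic acid library 2 the share was 78.2%, which argues against the background of that library as the whole cause. With the background as a covariate it was 75.5%. Leaving out acetic acid libraries 2 and 3 leaves 1 acetic acid library, so the share from that fit is not used here. Among all called genes the share went from 70.8% to 57% without acetic acid library 2 and 48.2% with the covariate. Higher calls went from 240 to 600 and 1002 there, and lower calls from 582 to 796 and 934. The share thus fell through more higher calls and not through fewer lower ones. Background as a part of the cause of the excess of decreases stays open. Among 2713 genes with a mean of at least 50 CPM, 110 lay 2 log2 units or more below their median change and 16 as far above, so 87.3% were below (95% interval 76.2 to 95.9, from 2000 resamplings of blocks of 20 adjacent genes). A share above 50% had been set beforehand as evidence against scaling, but the measure takes the median gene as fixed, which is itself a choice of scale. With library sizes only, decreases made up 55.4% of called changes of 2 log2 units or more (72 lower, 58 higher, 95% interval 38.7 to 70.4, against 81.9% with TMM) and 34.1% of those of 1 log2 unit or more (27.8 to 40.9). Scaling as the cause of this excess of decreases therefore stays open, and no biological explanation was tested for this pattern.

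Quorum-regulated exoproduct and catabolic genes were lower with acetic acid, and with library sizes only the 2 lists still held 24 lower genes, against 25 with TMM, which argues against the choice of scaling factors as the cause of these decreases. There 3 exoproduct genes and 1 catabolic gene were higher, against 0 with TMM. A hypothesis is that treated cultures were at an earlier stage of growth. A set of 27 stationary-phase genes, fixed before its values were seen, had a median log2 fold change of -0.72, below which lay 0.2% of 10000 random lists matched on expression. In edgeR, 7 fell and 0 rose, among them the ribosome modulation factor gene rmf (-2.14) and the glycogen genes glgA (-2.61) and glgX (-2.35), while rpoS stood at -0.87 with an adjusted p of 0.0609. It passed as lower in 13 of 22 alternatives, without acetic acid library 1 (-1.11) or 2 (-0.68) among them. The gene glgA did not pass without mock library 3 (-2.49) or acetic acid library 3 (-2.40) or with library sizes only (-2.03). Over the alternatives glgA ran from -5.54 to -2.03 and glgX from -5.97 to -1.80. Several of the 27 genes are neighbours, so the random lists make the result look firmer than it is, and ribosomal proteins had a median of 0.20 with 0 of 54 called. That count rests on the libraries and scaling, since 22 were higher without acetic acid library 2, 38 with the background as a covariate and 41 with library sizes only. Culture density at collection is not in the labels used here, so a growth delay and a direct effect of the acid remain open.

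With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split called 822 genes, 573 of them by 1 log2 unit or more, and was the 1 split to call any. The highest of the others called 0 of either kind in edgeR, with 2 to 883 genes at an unadjusted p under 0.05. For gene lists past camera's preset threshold the real split gave 3 and the highest of the others 18, and all 10 splits gave 3 or more, which points to a structure among the samples or to the preset correlation of 0.01, where the estimated ones ran from 0.024 to 0.909 and 0 lists passed with them. Neither was tested.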
